A study of Mus musculus with 12 samples.

How the data were processed

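Poly-A RNA was sequenced from 6 heart tube (HT) and 6 posterior second heart field (pSHF) samples of wild-type CD1 mouse embryos at E10.0. Per the labels' protocols, both tissues were dissected from the same embryo, libraries were made from 1 µg of total RNA with a TruSeq RNA version 2 kit, and single-end reads of 50 bases were made. By its design that kit does not mark strand, whereas the protocol calls the reads stranded; which is right is not given in the sources used here. Per the submitters' processing notes, STAR, DESeq2 and the build mm10 were used; their versions, the annotation and the counting tool are not given in the sources used here. The labels do not say whether each library came from its own embryo or from a pool, so p-values measure the spread between these libraries.

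Deposited values were of 2 kinds. Per the file headers and values, the first table held raw counts for 23324 gene symbols, 7080 of them at 0 in all libraries, with 233865 to 340434 counts per library. The second was the authors' DESeq2 comparison, with the deposited log2 fold change, its standard error, p-value and adjusted p-value, and a deposited signal per library, called normalized gene counts here, which the values show to be only in part gene counts divided by a size factor per library. In that signal 46.5 to 49.4% of values below 20.5 reads were whole multiples of one step per library within a tolerance of 0.01 reads. The steps gave each library's size factor and a rebuilt depth of 19089600 to 26287300 reads, but whole reads were not recovered for the other values, which carry a further factor whose origin is not given in the sources used here, so rebuilt reads are approximate. Columns name the tissue and a library code and no replicate number, so libraries were grouped by tissue only. The names of 27 genes had been turned into dates and were replaced through the gene identifier; 21345 of 21563 identifiers matched the gene name table. Coordinates are those of GENCODE for the mouse build GRCm38 (mm10), matched by gene identifier without version; its release need not be the authors'.

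The tests, gene lists and naming rule were fixed before the data were examined, with edgeR's quasi-likelihood test (version 4.0.16, TMM, filterByExpr) on the raw counts as the only main test. The raw table then proved to hold 1.08 to 1.30% of the rebuilt depth, with the antisense gene Peg3as holding the most counts. After the authors' deposited fold changes had been seen, but before any test was run, the normalized gene counts were therefore chosen to lead the report, with limma (version 3.58.1, trend) on log2 of the value plus a pseudocount of 1, for genes with a mean of at least 5 over the 12 libraries. Both analyses are reported. Adjusted p is Benjamini-Hochberg, with a threshold of 0.05. Gene lists (25 tested of 26 fixed; the sex chromosome list was used only to compare libraries) were tested with camera, preset correlation 0.01, two-sided, adjusted over the lists. Strand overlap was read from the annotation as shared exon bases on opposite strands, with a minimum of 100.

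Named genes follow a rule with 4 parts, applied to the normalized gene counts. The first takes the 10 largest and 10 smallest log2 fold changes among genes past the threshold, with at least 5 CPM in the higher tissue, a symbol that is not a predicted name, and full separation of the libraries. From each list the second takes the members with the 2 largest and 2 smallest log2 fold changes, whatever their sign. These must pass the threshold with at least 1 CPM in the higher tissue, and any members are taken where fewer than 4 do. The third always takes Gli1, Ptch1, Foxf1, Osr1, Isl1, Tbx5, Nkx2-5, Tnnt2 and Myh6. The fourth takes list members that go against the majority. Some genes that the rule takes are not reported here. Genes outside the rule are marked in the text as chosen after their values were seen.

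On simulated counts with 50 genes changed per fold, the limma fit on 14910 genes recovered 64% of 1.3-fold, 84% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes with 6 false calls. The edgeR fit on 3417 genes recovered 22%, 54%, 88% and 100% with 11 false calls. The simulation gave all genes the same dispersion, balanced the changes by direction and, for the limma fit, used known size factors. In the data far more genes differed and the scaling was uncertain, so these rates need not carry over. Alternatives to the edgeR fit that were planned were other normalizations (DESeq2 size factors, upper quartile), DESeq2 (version 1.42.0), limma-voom, other filters, removal of hemoglobin and mitochondrial-genome genes, a stricter threshold and leaving out each library. Alternatives to the limma fit (pseudocount, filter, scaling, rebuilt reads, removal of erythroid genes, library-code order as a block, each library left out) were chosen after seeing the data. R 4.3.3, SciPy 1.17.1 and pandas 2.3.3 were used.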

Results

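The series compared gene expression in 2 tissues of wild-type CD1 mouse embryos at E10.0. The heart tube (HT) holds the differentiating heart muscle, and the posterior second heart field (pSHF) is the mesoderm behind it, known as a source of cells for the atria and the atrial septum. The series title places the comparison within a study of how Hedgehog signaling affects the timing of differentiation. Poly-A RNA was sequenced from 6 HT and 6 pSHF libraries. In the deposited table of normalized gene counts, on which the values below rest, rebuilt depths were 20634400 to 25645400 reads in HT and 19089600 to 26287300 in pSHF. A second deposited table of raw counts held 233865 to 340434 counts per library and is described at the end. Values are mean normalized gene counts ± SD with n = 6 libraries per tissue, and fold changes are HT over pSHF on the log2(value + 1) scale, which understates changes of genes with few reads.

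Across the genes tested, libraries of one tissue correlated with each other at r = 0.982 to 0.990, and libraries of different tissues at 0.873 to 0.895; these are correlations across genes, which are not independent replicates. The first principal component held 82.7% of the variance. Of 14909 genes tested, 11676 (78.3%) passed an adjusted p of 0.05 in limma, 5708 with higher levels in HT and 5968 with higher levels in pSHF. More than 2-fold differences were found for 1995 of the genes higher in HT and 2032 of those higher in pSHF. The split by direction depended on scaling. With every library scaled to the same total, an alternative chosen after seeing the data, the median log2 fold change shifted by -0.25, and 3924 genes were higher in HT against 8160 in pSHF. Small differences are therefore to be read relative to that shift.

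Myl2 and Pln were higher in HT, and Gli1 and Foxf1 were higher in pSHF. Myl2 (ENSMUSG00000013936.8; mm10 chromosome 5, 122100951 to 122113472), the regulatory light chain of ventricular myosin, stood at 74284 ± 7499 in HT and 56.2 ± 35.5 in pSHF, a log2 fold change of 10.52 with a standard error of 0.27 and an adjusted p of 4.8e-14 in limma. Pln (chromosome 10, 53337667 to 53345987), the inhibitor of the sarcoplasmic calcium pump, stood at 10927 ± 928 in HT and 50.7 ± 26.1 in pSHF (log2 fold change 7.87). Gli1 (ENSMUSG00000025407.6; chromosome 10, 127329882 to 127341974), a transcription factor induced by Hedgehog signaling, stood at 43.2 ± 7.92 in HT and 2014 ± 80.2 in pSHF, a log2 fold change of -5.53 with a standard error of 0.098 and an adjusted p of 2.4e-15. Foxf1 (chromosome 8, 121084386 to 121088144), a forkhead factor of the mesoderm beside the foregut, stood at 14.4 ± 9.02 in HT and 2189 ± 337 in pSHF (log2 fold change -7.35). For each of these 4 genes every library of one tissue lay beyond every library of the other.

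**Figure D1:**
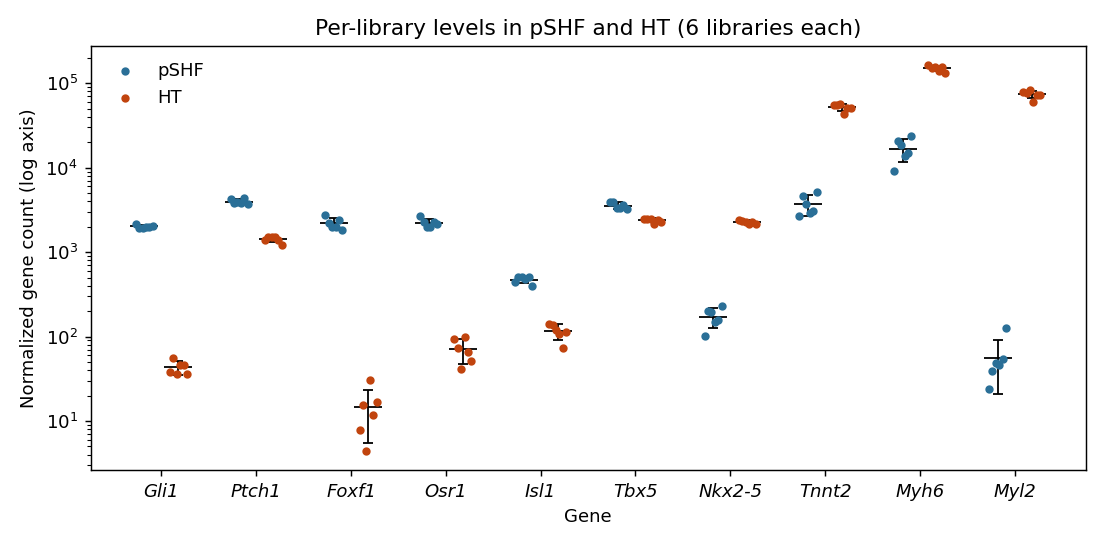
Normalized gene counts (log axis) of 10 genes, with a point for each of the 6 libraries per tissue, the mean as a horizontal mark and the SD as the error bar. Gli1, Ptch1, Foxf1, Osr1, Isl1 and Tbx5 were higher in pSHF, and Nkx2-5, Tnnt2, Myh6 and Myl2 were higher in HT.

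Among genes past the threshold with at least 5 CPM in the higher tissue, a symbol that is not a predicted name and libraries that separated fully by tissue, the 10 largest log2 fold changes toward HT belonged to Myl2, Pln, Nppa (6.94), Irx4 (6.90), Nppb (6.88), Myh7 (6.68), Myl3 (5.79), Cav3 (5.66), Cited1 (5.53) and Nrap (5.36). Nppa and Nppb encode natriuretic peptides, Irx4 is a ventricular transcription factor, and Myh7 encodes beta-myosin heavy chain. The 10 largest toward pSHF belonged to Nkx2-1, Nkx6-1, Rspo4, Cxcl13, Wnt7b, Msc, Pax1, Foxd1, Hoxb5 and Hoxd3. Several of these were near the detection limit in HT, so their order depends on the pseudocount (with 5 in place of 1, 6 of the 10 stayed among the 10 largest, against 10 of 10 toward HT), and levels are given in place of folds. Nkx6-1 was listed at 0 in all 6 HT libraries and at 438 ± 63.5 in pSHF. Nkx2-1, a factor of the lung and thyroid endoderm, stood at 0.352 in HT and 621 ± 120.1 in pSHF, Rspo4 at 1.44 and 693 ± 141, Cxcl13 at 1.08 and 591 ± 162, and Msc at 0.941 and 330.1 ± 54.7. Wnt7b stood at 5.27 ± 4.48 in HT and 1147 ± 161 in pSHF, Pax1 at 0.948 ± 1.05 in HT and 392 ± 253 in pSHF, Foxd1 at 2.68 ± 4.24 in HT and 486 ± 92.6 in pSHF, Hoxb5 at 2.85 ± 2.84 in HT and 576 ± 72.2 in pSHF and Hoxd3 at 2.01 ± 2.79 in HT and 437 ± 117 in pSHF.

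Genes of the contractile apparatus were higher in HT. Of 28 sarcomere genes, 27 were higher in HT, with a median log2 fold change of 3.95 over the list. Tnnt2 (chromosome 1, 135836354 to 135852260), cardiac troponin T, stood at 52116 ± 4955 in HT and 3706 ± 1008 in pSHF, and Myh6 (chromosome 14, 54941921 to 54966927), alpha-myosin heavy chain, at 150384 ± 11196 in HT and 16792 ± 5181 in pSHF. The smallest differences in the list among genes that passed were those of Myl7 (3.08) and Tpm1 (1.97), and Myom2, chosen after its values were seen, did not pass (14.1 ± 5.96 in HT and 8.81 ± 3.94 in pSHF; adjusted p = 0.0797). Of 20 genes of calcium handling and conduction, 19 were higher in HT and 1 in pSHF, Trdn being among the former (4.30). The difference of Gja1 was small (0.23) and turned to -0.02 with equal library totals. All 13 genes of chamber myocardium were higher in HT, including Pam (2.90) and Bves (2.22). Of 28 genes of mitochondrial energy metabolism, 27 were higher in HT, from Cox8b (5.24) and Ckmt2 (4.74) to Ndufa4 (0.86) and Ndufb5 (0.84). With camera's preset correlation the adjusted p was 3.4e-13 for sarcomere genes, 5.1e-08 for calcium handling, 1.1e-07 for chamber myocardium and 3.4e-13 for mitochondrial genes. These calls did not hold with an estimated inter-gene correlation, where the adjusted p = 0.227 for sarcomere, adjusted p = 0.176 for calcium handling and adjusted p = 0.0663 for both chamber myocardium and mitochondrial genes. The same libraries differed in blood content: erythroid genes held 1.66 to 7.10% of the counts in HT and 0.351 to 0.694% in pSHF.

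**Figure D2:**
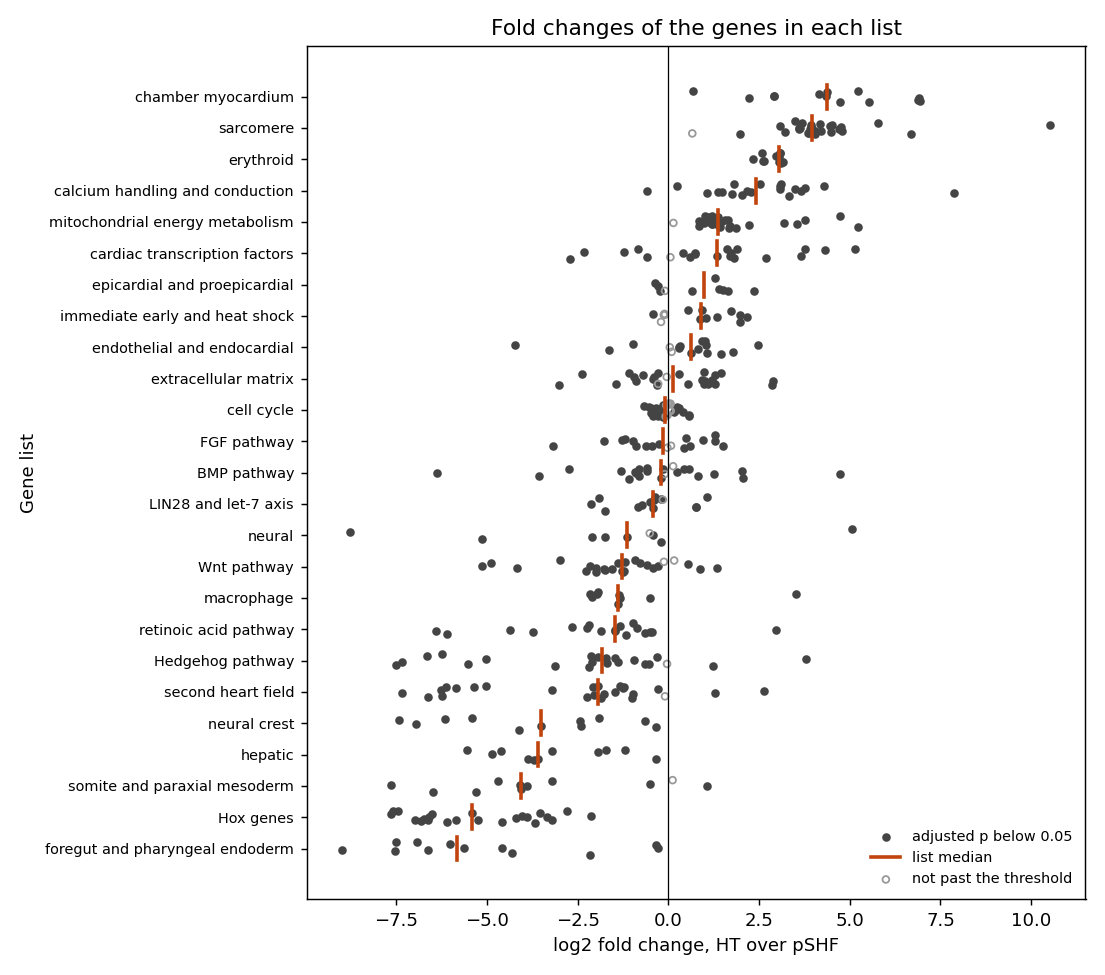
Log2 fold changes, HT over pSHF, of the tested genes of 25 lists, with a point per gene, filled where the adjusted p was below 0.05, and a bar at the list median. Sarcomere and chamber genes lie to the right (higher in HT), and Hox genes lie to the left (higher in pSHF).

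Heart transcription factors went both ways. Of 21 such genes, 15 were higher in HT and 5 in pSHF. Nkx2-5, required for heart muscle differentiation, stood at 2265 ± 107 in HT and 172 ± 45.8 in pSHF (log2 fold change 3.76), Hopx at 3166 ± 226 in HT and 92.8 ± 34.5 in pSHF and Hand1 at 1290.3 ± 163 in HT and 67.5 ± 22.8 in pSHF. Those higher in pSHF included Tbx2 (-2.71), Tbx3 (-2.32), Shox2 (-0.83) and Tbx5 (-0.58). Tbx5, mutated in Holt-Oram syndrome, stood at 2376 ± 126 in HT and 3564 ± 324 in pSHF. The camera adjusted p of the list was 0.00477, and the adjusted p = 0.265 with an estimated correlation. Of 25 second heart field genes, 22 were higher in pSHF and 2 in HT, with an adjusted p of 4.1e-07 in camera and of 0.00833 with an estimated correlation. Isl1, the classical marker of the field, stood at 115 ± 24.5 in HT and 472 ± 46 in pSHF (log2 fold change -2.05), and Osr1, needed for the atrial septum, at 70.2 ± 22.4 in HT and 2212 ± 257 in pSHF (-5.01). Hoxb1 stood at 0.495 in HT and 133 in pSHF. The 2 genes higher in HT were Sall1 (1339 ± 98.8 in HT and 216 ± 44.3 in pSHF) and Fgf8, whose levels were low in both tissues (10.5 ± 6.11 in HT and 3.73 ± 2.72 in pSHF). Markers of some other cell types moved with the list: all 12 endoderm, all 11 neural crest and 9 of 11 somite genes were higher in pSHF. The somite list had 1 gene higher in HT, and all 13 erythroid genes were higher in HT.

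Genes of the Hedgehog pathway were mostly higher in pSHF. Of 22 tested, 19 were higher in pSHF and 2 in HT, with a camera adjusted p of 1.5e-06 and an adjusted p of 0.0383 with an estimated correlation. The receptor gene Ptch1 (chromosome 13, 63508328 to 63573598), itself induced by the pathway, stood at 1425 ± 109 in HT and 3975 ± 253 in pSHF, a log2 fold change of -1.48. The ligand gene Shh was at 1.35 ± 1.94 in HT and 335 ± 54 in pSHF. Hhip, Gli2 and Gli3, named here after their values were seen, had log2 fold changes of -6.64, -3.12 and -2.18. The genes that went the other way were Scube2, which takes part in ligand release (503 ± 75.9 in HT and 36.6 ± 12.7 in pSHF), and the ligand gene Dhh (128 ± 10.6 in HT and 53.8 ± 6.83 in pSHF). Foxf1, Foxf2 and Osr1 are in this list and in the second heart field list, and Shh is also in the foregut endoderm list, so the lists are not independent. Endoderm markers moved with the pathway genes: all 12 tested genes of that list were higher in pSHF, among them Nkx2-1 at 0.352 in HT and 621 in pSHF and Foxa1 at 1.03 and 334.

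Retinoic acid, Wnt and Hox genes were likewise higher in pSHF. Of 18 retinoic acid genes, 17 were higher in pSHF, with Stra6 at 23.7 ± 7.08 in HT and 2008 ± 142 in pSHF and Crabp2 at 38.5 ± 14.7 in HT and 2596 ± 328 in pSHF; Aldh1a1, at 496 ± 75 in HT and 65.3 ± 22.9 in pSHF, went the other way. Of 26 Wnt genes, 21 were higher in pSHF and 3 in HT. Sfrp2 had a log2 fold change of -5.14, Wnt6 of -4.88 and the target gene Axin2, chosen after its values were seen, of -2.26, and Rspo3 (1.34), Sfrp5 (0.87) and Wnt11 (0.55) were higher in HT. All 23 Hox genes tested were higher in pSHF. Camera gave adjusted p of 2.3e-06 for retinoic acid, 9.2e-06 for Wnt and 1.2e-08 for Hox genes, and with an estimated correlation these were 0.0248, 0.0383 and 0.0383. FGF and BMP genes did not move one way as lists. Of 18 FGF genes 7 were higher in HT, including Spry4 (579 ± 62.8 in HT and 205 ± 27.4 in pSHF) and Fgf9 (1.28), and 9 in pSHF, including Fgfr2 (-1.77) and Fgfr4 (-3.17); the camera adjusted p was 0.425. Of 23 BMP genes 8 were higher in HT, including Bmp10 (4.72), Bmp2 (2.07) and Bmp7 (2.03), and 13 in pSHF, including the antagonists Grem1 (-6.37) and Chrd (-3.55), with a camera adjusted p of 0.237. Markers of other cell types moved with the retinoic acid, Wnt and Hox genes: all 12 endoderm, all 11 neural crest, 9 of 11 somite and 7 of 9 neural genes were higher in pSHF.

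Lists of developmental timing, the cell cycle and the matrix showed smaller or mixed differences. Of 14 genes of the LIN28 and let-7 axis, which governs developmental timing in nematodes, 10 were higher in pSHF and 3 in HT. Hmga2, a let-7 target, stood at 6861 ± 520.2 in HT and 29935 ± 2223 in pSHF (log2 fold change -2.13). Lin28a and Lin28b, chosen after their values were seen, had log2 fold changes of -1.75 and -0.72, and Arid3b (1.07), Sall4 (0.77) and Arid3a (0.76) went the other way. Arid3a in HT ranked by library as the erythroid share did, from 2242 in MR25 (1.66%) to 3564 in MR28R (7.10%). Every HT library still lay above every pSHF library (1591 ± 101 in pSHF), and the part of blood content in its difference was not tested. The camera adjusted p of this list was 0.0435, and the adjusted p = 0.391 with an estimated correlation; the call was also lost without HT library MR30 (0.0522) or pSHF library MR17 (0.0542). Of 30 cell cycle genes 7 were higher in HT, with Mki67 at 0.57 and Ccna2 at 0.56, and 15 in pSHF, with Cdk4 at -0.66 and Tyms at -0.54. None of the 30 differed by more than 2-fold, and the camera adjusted p was 0.191. With equal library totals the list passed (0.0224) and Mki67 did not (0.0552). In HT, Mki67 levels ranked by library as the erythroid share did, from 14292 in MR25 (1.66%) to 32677 in MR28R (7.10%), against 13772 ± 1844 in pSHF. Its difference therefore cannot be told apart from one in blood content. Of 26 extracellular matrix genes 13 were higher in HT, led by Hapln1 (2.89) and Postn (2.87), and 11 in pSHF, led by Lox (-3.02) and Col1a2 (-2.37), with a camera adjusted p of 0.357.

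Markers of other cell types also differed between the dissections. All 13 erythroid genes were higher in HT, Hbb-bh1 at 181087 ± 94298 in HT and 18218 ± 4330.5 in pSHF and Slc4a1 at 24083 ± 13678 in HT and 2482 ± 746 in pSHF. Of 17 endothelial and endocardial genes 12 were higher in HT, among them Nfatc1 (2.48) and Tek (1.79), and 3 in pSHF, Cldn5 (-4.22), Sox17 (-1.63) and Sox18 (-0.97). Of 10 epicardial genes 6 were higher in HT, Upk1b most (2.37), and 3 in pSHF, Bnc1 (-0.35), Sema3d (-0.28) and Wt1 (-0.23). All 12 genes of foregut and pharyngeal endoderm, such as Foxa1 (1.03 ± 1.08 in HT and 334 ± 54.8 in pSHF), and all 11 neural crest genes, such as Tfap2b (3.81 ± 3.02 in HT and 527 ± 61.1 in pSHF), were higher in pSHF. Of 9 neural genes 7 were higher in pSHF, including Dcx (-5.13), and 1 in HT, Sox3 (156 ± 16.7 in HT and 3.84 ± 1.46 in pSHF). All 11 hepatic genes were higher in pSHF, with Afp varying widely (213 ± 341 in HT and 2844 ± 2245 in pSHF). Of 11 somite genes 9 were higher in pSHF, including Meox2 at 1.25 ± 1.75 in HT and 163 ± 33.9 in pSHF, and 1 in HT, Mesp2, at 7.7 ± 4.04 in HT and 2.88 ± 1.29 in pSHF. Of 9 macrophage genes 8 were higher in pSHF, including C1qb (-2.14), and 1 in HT, Lyz2 (3.51), which shares much of its sequence with Lyz1 and is therefore uncertain. Of 14 immediate early and heat shock genes 9 were higher in HT, including Fos (1.99), and 1 in pSHF, Ier2 (-0.43).

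Camera called 20 of the 25 lists, and 6 of them held with an estimated correlation. The cell type lists had camera adjusted p of 1.3e-04 for erythroid, 0.00861 for endothelial, 0.106 for epicardial, 6.5e-05 for endoderm, 4.4e-05 for neural crest, 0.0359 for neural, 0.0223 for hepatic, 0.0136 for somite, 0.0331 for macrophage and 0.0331 for immediate early genes. With an estimated correlation, neural crest kept its call (adjusted p = 0.021), and the others that had passed did not: erythroid had an adjusted p of 0.380, endothelial 0.391, endoderm 0.0593, neural 0.265, hepatic 0.470, somite 0.265, macrophage 0.251 and immediate early genes 0.138. Counts adjusted over the list alone equalled those over all genes tested except for the mitochondrial list (28 higher in HT), the Wnt list (4 higher in HT and 22 in pSHF) and the BMP list (14 higher in pSHF).

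In the authors' deposited table of their own comparison, 11951 of 18214 genes with an adjusted p were below 0.05, 5768 higher in HT and 6183 higher in pSHF. Of the 11676 genes that passed in limma, 11469 also passed there in the same direction and 0 in the opposite direction. Both rest on the same libraries and the same deposited scaling, so this match was largely fixed in advance and is not independent evidence.

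The deposited raw count table gave fewer calls and, for part of the genes, other directions. In edgeR's quasi-likelihood test, the planned test, 1629 of 3370 genes passed, 850 higher in HT and 779 in pSHF, with 410 and 219 differing by more than 2-fold. These counts depended on the processing: DESeq2 gave 893 and 642 by over 2-fold, and edgeR called 2889 genes without a filter (1126 and 863 by over 2-fold) and 2761 with a filter of CPM 1 (1077 and 751). Of the calls of the planned test, 1381 were of genes matched to the authors' deposited table; 1021 of them passed there in the same direction and 181 in the opposite one. Genes without opposite-strand exon overlap in the annotation held a median of 0.381% as many raw counts as rebuilt reads. Among 766 genes whose exons overlapped those of an opposite-strand gene by at least 100 bases, raw-table fold changes correlated with the normalized fold changes of the same gene at r = 0.33 and with those of the partner at r = 0.71, across genes that are not independent replicates. For 1471 genes without such overlap the correlation with the same gene was 0.91. Camera on the raw table called 7 lists: sarcomere, calcium handling, chamber myocardium, mitochondrial and erythroid genes higher in HT, and second heart field and Hox genes higher in pSHF. These calls covered only the members that passed the count filter. They were 24 of 28 sarcomere, 11 of 20 calcium handling, 4 of 13 chamber and 18 of 28 mitochondrial genes. For erythroid genes they were 5 of 13, for second heart field genes 6 of 25 and for Hox genes 6 of 31. Without a filter camera called 13 lists. Fry, which tests a list against no change and not against the other genes, called 15. The erythroid call was lost with an estimated correlation (adjusted p = 0.14), and 8 lists had no gene that passed the count filter.

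**Figure D3:**
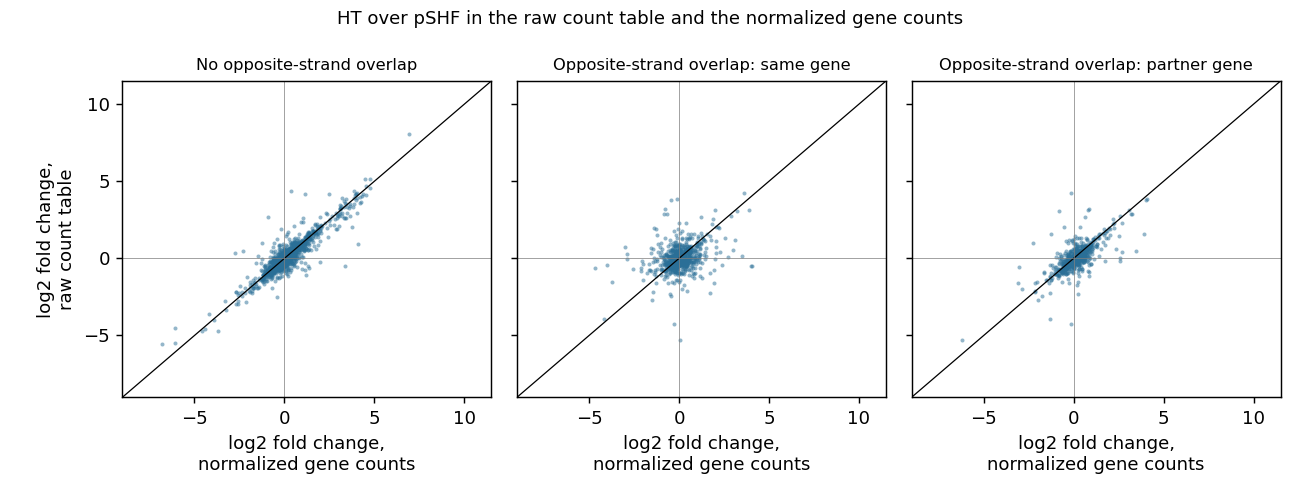
Log2 fold changes (HT over pSHF) in the raw count table against those in the normalized gene counts, with a point per gene and the line of equality. The left panel shows genes without opposite-strand exon overlap (r = 0.91), the middle panel overlapping genes against themselves (r = 0.33), and the right panel the same genes against their opposite-strand partner (r = 0.71).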

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

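The tests in this part were chosen after the results were seen, apart from the comparison of each library with the rest of its tissue. In 228 groups of 6 libraries, 17 values lay farther from the rest than Dixon's limit for 6 values, where chance alone gives about 11.4.

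In HT library MR28R, Myl7 (32991), Cav3 (551.55), Ndufa4 (4099.1), Hopx (2720.3) and Cdk4 (9572.8) were below the other HT libraries and Nkx2-1 (2.113) was above them. That library also had the highest erythroid share of the HT libraries, 7.10%. In other HT libraries Foxd1 stood at 11.047 in MR26, Crabp2 at 66.574 in MR29, Rspo3 at 789.89 in MR27 and Tfap2b at 9.8059 in MR30, each the highest of its tissue, and Sema3d was lowest in MR29 (761.48). In pSHF, Nkx2-1 (849.39) and Tyms (2402.0) in MR13 and Grem1 (723.13) in MR16 were highest, Sfrp5 was highest in MR14 (139.96), Hand1 in MR13 (24.316) was lowest, and Myl2 in MR18 (125.46) was highest.

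Heart muscle transcripts were present in every pSHF library: the median sarcomere gene stood at 4.59 to 8.70% of its HT level. Carry-over of whole heart tube tissue would set a floor at one share for every abundant heart tube transcript, but of 52 genes of the sarcomere, calcium handling and chamber lists with a mean of at least 1000 in HT, 7 stood below 0.5 of that median in each of the 6 pSHF libraries. Myl2 stood at 0.032 to 0.169% of its HT level, which bounds such carry-over below the share the median would need. Muscle of the atrial or inflow part, either within the pSHF or dissected along with it, may contribute. Genes more typical of atrial muscle (Myl7, Myl4, Myh6, Kcnj3, Kcnj5) stood at a median of 6.38 to 15.6% of the HT level in the pSHF libraries. Genes more typical of ventricular muscle (Myl2, Irx4, Myh7, Myl3, Hey2) stood at a median of 0.643 to 1.48%. The sets did not part gene by gene. By tissue means, ventricular Hey2 stood at 13.1% of its HT level, above Myl4 (8.34%), Kcnj5 (10.3%), Myh6 (11.2%) and Myl7 (12.03%). Of the atrial set only Kcnj3 (20.96%) stood above Hey2. The other ventricular genes ran from 0.0757% (Myl2) to 1.89% (Myl3). Nppa of the chamber list, in neither set, stood at 0.977%. Both sets of genes and both tests were chosen after the values were seen, so atrial muscle and low expression in progenitors cannot be told apart, and tissue itself stays open as untested.

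The raw count table differed from the normalized gene counts in level and direction. A shallower count of the same reads is argued against by 36 genes with at least 1000 rebuilt reads that had more raw counts than rebuilt reads. Counting of reads on the strand opposite to each gene is a candidate explanation: for overlapping genes, raw-table fold changes followed the opposite-strand partner at r = 0.707, and the difference from the correlation with the gene itself was 0.378 (95% bootstrap interval 0.218 to 0.526). The kit named in the labels does not mark strand by design, while the protocol calls the reads stranded, so the explanation holds only if the protocol's wording is right. Opposite-strand counting of reads without strand would leave genes without overlap a large share of their reads. The 7491 such genes held a median of 0.381% as many raw counts as rebuilt reads (10th to 90th percentile 0.213 to 0.793%). For these genes that argues against reads without strand, if the same reads were counted. No biological explanation was tested.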

How the results depend on the processing

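Alternatives to the limma results, and the tests of other splits, were chosen after seeing the data; those to the edgeR results were planned. No paired analysis was possible because the columns carry no replicate numbers and no label says which libraries pair. The exception was an added limma fit with the order of the library codes as a block. It called 11612 genes, 11448 of them also called without the block. As a hint from the data only, 4 of 6 HT libraries and 6 of 6 pSHF libraries deviated most like the library of the same code order in the other tissue. Mean r was 0.089 for pairs in code order and -0.018 for others. Because deviations were taken from the tissue mean, the mean for others is tied to that for pairs and adds no separate evidence. The 5 limma counts stayed within 1.5 times under every alternative (genes differing 10538 to 12277), with 11422 to 11605 when 1 library was left out. With equal library totals 9892 calls kept their direction and 210 reversed; Gja1 moved from 0.23 to -0.017. In camera, the estimated correlation left 6 of 20 lists. Fry passed all 25 lists of the normalized gene counts, including FGF (adjusted p 3.4e-05), BMP (2.0e-05) and cell cycle (0.00235). Counting each list under each alternative, 22 list calls on the normalized gene counts were lost and 6 gained. On the raw table, DESeq2 called 893 genes higher in HT and 642 higher in pSHF by over 2-fold. Without a filter edgeR called 2889 genes (1497 higher in HT, 1392 in pSHF, 1126 and 863 by over 2-fold), and with a filter of CPM 1 it called 2761 (1483, 1278, 1077 and 751), more genes being tested. Camera's 7 lists became 13 without a filter, and fry called 15. Gja1 in the raw table was -0.043 with upper-quartile normalization and -0.039 (without pSHF library MR14) to 0.154 with 1 library left out; the cause was not tested. The raw table held at most 340434 counts per library, and 3370 genes passed its filter.

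Other splits of the 12 libraries into 6 and 6 were fitted 100 times, the real one included. For each limma count 1 of the 100 splits gave as many, the real one: 11676 against at most 5541 in another split, 5708 and 5968 against 2911, and 1995 and 2032 against 1016. Only 100 of 462 possible splits were fitted, and every other split puts part of the tissue difference within its groups. The real split was thus favored in advance, and the comparison cannot exclude chance. The highest other splits exchanged 1 library per tissue and so kept most of the tissue difference; splits that exchanged more called at most 1 gene. For the limma lists 2 of 100 gave as many (20 against 21), and splits exchanging more than 1 library called up to 19 lists, so the number of lists called does not set the tissues apart from other splits. For each edgeR count (1629, 850, 779, 410 and 219) 1 of 100 did, with 0 in the highest other split. For the edgeR lists 15 of 100 gave as many (7 against 8), so chance is not excluded there.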

Other observations

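Several genes outside the comparisons above stood out. Lyz1, chosen after its values were seen, stood at 111 ± 16.2 in HT and was listed at 0 in all pSHF libraries, while Lyz2 stood at 596 ± 43.3 in HT and 51.4 ± 5.24 in pSHF; the 2 genes are near-identical copies, so the assignment of reads between them is uncertain. Of the genes with the most counts in the raw table, Tstd2 had a raw-table log2 fold change of 3.81, its own normalized one was -0.45, and that of Tmod1, an opposite-strand gene that overlaps it by 1287 bases, was 4.02.

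Sex-linked transcripts varied alike in both tissues; the tests of this pattern were chosen after the values were seen. Summed Ddx3y, Eif2s3y, Kdm5d and Uty levels, taken in the order of the library codes, correlated between the tissues over 6 pairs. Pearson's r was 0.965 (exact permutation p = 0.00972, two-sided) and Spearman's rho 0.943 (exact permutation p = 0.0167). Without the 2 pairs whose HT sums lay farthest from the HT median (MR25 and MR26), r was 0.997. That value rests on 1 pair: the HT sums left were 3776, 3898 and 3900, and 5672 in MR30. It therefore does not show that the relation is robust. The Y-linked correlation is 1 of 2 relations computed between code-ordered libraries. The other was the correlation across genes of deviations from the tissue mean. It was 0.062 to 0.115 for code-ordered pairs and -0.088 to 0.085 for other combinations, with no p computed. Libraries in the same code order may therefore come from the same embryos, although no label says so. A single embryo per library is argued against: it would leave Y-linked genes near 0 or at one male level, but their summed levels ran from 1598 to 5672, and the highest library stood at 2.89 to 3.65 times the lowest of its tissue for each of the 4 genes, past the 99th percentile of autosomal genes of similar level (1.90 to 2.72). In the raw table Tsix stood at 2 counts in the library with the most Y-linked transcripts of each tissue and at 473 to 1573 in the other 10, which marks female cells only if that table holds the strand opposite to each gene. Whether embryos were pooled or samples mixed later stays open.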
